A study of Mus musculus with 2 samples.

How the data were processed

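Epididymal white adipose tissue, the visceral fat pad beside the epididymis, was taken from male C57BL/6 mice on 2 diets. Per the labels, diets were started at 9 weeks of age, and one sample came from a chow-fed mouse and the other from a mouse that received a high-fat diet over 7 weeks. Total RNA was extracted with Trizol, and 10 µg was turned into biotin-labelled cRNA for an Affymetrix mouse array, per the labels' protocols. An array of this type carries several short probes for each transcript, which are summarised into a single value per probe set. Each diet had 1 array, so the design has no replicates and no estimate of the spread between animals.

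The deposited table holds 1 linear intensity per probe set and array for 45037 probe sets, with no detection calls. The summary algorithm and the scaling used by the authors are not given in the sources used here. The deposited intensities ran from 0.1 to 10726.6 on the chow array and from 0 to 11559.7 on the high-fat diet array. Their means after trimming 2% at each end were 99.6 and 99.6, as a scaling of each array to one common target would leave them. The medians of the log2 intensities were 5.38 and 5.35, a difference of -0.03. Because this was under the limit of 0.1 log2 set beforehand, intensities were used as deposited, with no further centring. If the total RNA content per cell or the overall transcript level differed between the samples, a scaling of this kind would remove it.

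Probe sets were named from the platform annotation of 2016. Of the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none here. Only those with 1 symbol were used for genes, and 34741 of them matched the RefSeq gene table by gene ID, which changed 0 symbols. They named 18193 genes. In the gene lists, 2 symbols were replaced by the current symbol of the same gene. No genome build is named for the probe sets, and positions are not given for this reason.

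Each array's 40th percentile of all probe sets, an intensity of 28.6 on the chow array and 27.9 on the high-fat diet array, served as a floor for weak signal. A probe set counted as measured where it reached the floor on at least 1 array, and a value under the floor was raised to it before log2 was taken. The brightest array values lay 375 and 414 times above the floor. Where a gene had several measured probe sets, the one with the highest mean log2 intensity over both arrays was used, a choice that does not look at the difference between the diets. This gave 14066 measured genes, 12496 of them above the floor on both arrays and 1570 on 1 array only. For the latter the difference is a bound, and it is written as at least N-fold. All differences are high-fat diet minus chow on the log2 scale.

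With 1 array per diet, no test of the diet is possible and none was made. Genes were counted by size alone, at 2-fold or more. As a yardstick of part of the measurement error, the diet difference of each probe set was compared with the mean difference of its gene. The pooled SD around that mean was computed over 5196 genes with 2 or more probe sets above the floor on both arrays. It covers probe and annotation error on these arrays and contains no difference between animals and no error shared by all probe sets of a gene. The number of arrays limits the precision of all values.

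The gene lists, 40 in all, were fixed before the data were examined, together with the rules for the floor, the probe set, the size threshold, the names and most of the alternatives. They were named macrophage, lipid-associated macrophage, inflammatory cytokine and chemokine, T and NK cell, B cell, neutrophil, mast cell, MHC class II, mature adipocyte, adipokine, fat mass expansion, de novo lipogenesis, triglyceride synthesis and lipid droplet, lipolysis, fatty acid oxidation, oxidative phosphorylation, TCA cycle and pyruvate, branched-chain amino acid breakdown, brown and beige adipocyte, insulin signalling and glucose use, extracellular matrix, adipocyte progenitor and fibroblast, endothelial, smooth muscle and pericyte, unfolded protein response, antioxidant, NADPH oxidase, hypoxia, lysosome, cholesterol synthesis, interferon response, proliferation, circadian clock, immediate early, epididymis, testis germ cell, mesothelial, skeletal muscle, red blood cell and reference gene. For each list with 5 or more measured members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart at or below the 2.5th or at or above the 97.5th percentile. The percentile describes these 2 arrays and is not a p-value, since genes of a list vary together within a sample.

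The genes named in the text followed a rule. It took the 10 largest differences in each direction among genes above the floor on both arrays whose measured probe sets all differed the same way, and the 5 largest bounds in each direction among genes above the floor on 1 array. It also took up to 4 members per list with the largest absolute difference above the floor on both arrays, and a short set of adipose genes fixed beforehand whatever their values. Predicted transcripts were counted but not named.

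The scripts were tested on simulated data with noise of 0.3 log2 SD, the same at every intensity and without differences between animals. The changed genes were drawn only from genes bright on both arrays. The shares below therefore check the scripts and do not estimate false calls on the real arrays. Of 100 genes changed by 1.5 log2 units, 96% were called at 2-fold, against 5% of 100 genes changed by 0.5 and 0.075% of 13406 unchanged genes. Of 200 random lists of unchanged genes, 4% stood apart, against 99.5% after a shift of 0.4.

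The alternatives were 4 other scalings (centring on the median, quantile normalization, intensity-dependent centring by lowess, and centring on the reference genes), floors at the 25th and 60th percentiles or none, a pseudocount of 50, 3 other choices of probe set (the mean of all, only plain probe sets without an s, x or a in their suffix, and the one with the smallest difference), sizes of 1.5-fold and 3-fold, random lists not matched on level, and lists without their most different member. Some restrictions of the genes and of list members were added after the data were seen. In the closing tests, 95% intervals of list medians came from resampling the genes of a list 10000 times; they cover the choice of genes and no difference between animals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used. Probe sets with several symbols or none entered no comparison between genes.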

Results

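Gene expression in epididymal white adipose tissue was profiled on 1 array per diet, 1 from a chow-fed mouse and 1 from a mouse after 7 weeks of high-fat feeding, to characterise how the fat pad differs between the diets. Of 45037 probe sets, 60.1% lay at or above the floor on the chow array and 60.0% on the high-fat diet array. Over the 24727 probe sets above the floor on both arrays, log2 intensities of the 2 arrays correlated across probe sets with Pearson's r = 0.97, a value across features that are not independent replicates. Neither diet has a replicate. No difference below could be set against the spread between animals, and "higher" and "lower" describe these 2 samples only. As a measure of probe error, the diet difference of single probe sets had a pooled SD of 0.32 log2 units around the mean difference of their gene. This SD was 0.37 for genes with a mean intensity under 100, 0.29 between 100 and 400, and 0.20 above 400. It leaves out error shared by all probe sets of a gene.

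Most genes had similar intensities on both diets, with 83.0% of the 14066 measured genes within 0.5 log2 units. On the high-fat diet 163 genes were 2-fold or more higher and 187 were 2-fold or more lower. Of the higher genes 116 were above the floor on both arrays, as were 117 of the lower genes. Among higher genes that had another measured probe set, the other probe sets differed the same way in 53 of 68, and by 2-fold or more in 18. Among lower genes they differed the same way in 42 of 55, and by 2-fold or more in 7. Centring on the reference genes in place of using the deposited scale changed the split to 124 higher and 251 lower.

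Among genes above the floor on both arrays whose probe sets differed the same way, the most strongly higher on the high-fat diet were Fgf13, a member of the intracellular fibroblast growth factor family, Sfrp5, a secreted modulator of Wnt signalling, and Mest, an imprinted gene linked to adipocyte enlargement. Fgf13 had an intensity of 55.8 on chow and 749.5 on the high-fat diet, 13.4-fold higher, and its other probe set differed by 3.07 log2 units. Sfrp5 was 10.8-fold higher, from 105.1 to 1130.8, with a difference of 1.86 in its other probe set. Mest was 7.60-fold higher, from 504.4 to 3831.5, in its only measured probe set. Next came Mtarc1, a mitochondrial reductase, at 5.47-fold, Crtac1, a matrix protein, at 5.32-fold, and Thbs1, the matrix glycoprotein thrombospondin, at 5.26-fold. The ubiquitin-like gene Ubd was 4.94-fold higher, S100a8, a calcium-binding protein of myeloid cells, 4.82-fold, Srpx2 3.85-fold and Paqr9 3.57-fold. Both probe sets of Thbs1, of Mtarc1 and of Paqr9 were 2-fold or more higher. Of the other 3 probe sets of Crtac1, the one above the floor on both arrays differed by 0.11, and those above it only on the high-fat diet differed by at least 0.71 and 0.47. Genes above the floor only on the high-fat diet array included Pla2g2e, a secreted phospholipase, at least 5.20-fold higher, Duoxa1, at least 4.72-fold, Cfap126, at least 4.21-fold, Npy, the gene of neuropeptide Y, at least 3.66-fold, and Tstd3, at least 3.21-fold.

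Among the same kind of genes, Cyp2f2, a cytochrome gene of xenobiotic metabolism, was the most strongly lower. It was 11.1-fold lower on the high-fat diet, from 806 to 72.5. Angpt1, which encodes a ligand of the endothelial Tek receptor, was 4.04-fold lower, and its other probe set, above the floor only on chow, differed by at least -0.71. Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, was 3.42-fold lower, from 1583.6 to 462.4, with a difference of -0.79 in its other probe set. Slc1a3, a glutamate transporter, was 3.28-fold lower, but of its 4 other probe sets above the floor on both arrays 1 differed by -1.57 and 3 by only -0.44, -0.83 and -0.86. The complement gene C2 was 3.09-fold lower, with differences of -1.52 and -0.64 in its other probe sets. Ttr, the carrier of thyroid hormone and retinol, was 3.80-fold lower to 28.6, just above the floor. Fastk was 3.67-fold lower, Rtbdn 3.26-fold, Sult1e1, an oestrogen sulfotransferase, 2.76-fold and Fen1 2.74-fold. Rtbdn, at 28 on the high-fat diet, also lay just above the floor, and it was under 2-fold in 2 alternatives. Genes above the floor only on chow included Apoa2, an apolipoprotein, at least 7.68-fold lower, Acsm3, at least 4.38-fold, Pcyt2, an enzyme of phosphatidylethanolamine synthesis, at least 3.87-fold, and Cyp26b1, which degrades retinoic acid, at least 3.68-fold. Apoa2 and Ttr are abundant in liver, and a list of 14 other liver genes, chosen after the data were seen, had a median difference of -0.35 (0.85th percentile), with 9 lower, 5 of them above the floor only on chow, and 5 higher, while 5 more were below the floor on both arrays. Pcnt was at least 9.72-fold lower in the brighter of its probe sets, while the other differed by 0.079, so its direction depends on the probe set.

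Genes that go with fat mass expansion were higher on the high-fat diet. All 7 measured members of this list were higher, 2 of them by 2-fold or more, and the median difference was 0.63 log2 units, at the 99.96th percentile of random lists. Beside Mest and Sfrp5, Npr3, the clearance receptor of natriuretic peptides, was 1.57-fold higher and Lep, the gene of the satiety hormone leptin, was 1.55-fold higher, from 2001.2 to 3099.8. Among adipokines, 9 of 15 were higher and the median difference of 0.15 was within the range of random lists (92.3rd percentile), but at the 98.9th percentile under quantile normalization and the 98.7th under lowess centring. Angptl4, a secreted inhibitor of lipoprotein lipase, was 2.36-fold higher and Rarres2, which encodes chemerin, 1.67-fold higher, although the probe sets of Rarres2 did not all agree in direction. Agt, which encodes angiotensinogen, was 2.55-fold lower and Igf1 1.77-fold lower in 4 probe sets of one direction. Adipoq, the gene of adiponectin, differed by 0.06 at 8372.1 and 8718.4, and Retn, the gene of resistin, by -0.07. The mature adipocyte list as a whole had a median difference of 0.06 (52.6th percentile), with 15 of 17 members within 2-fold. Its member Fabp4 was the brightest value on both arrays, at 10726.6 and 11559.7, and Adipoq and Retn were also near the top of the range. Whether signals this bright were compressed was not tested, so their small differences do not show an unchanged level. In that list Klf15, a transcription factor of the fed and fasted response, was 2.59-fold lower, Aqp7, the glycerol channel, was 2.04-fold higher (0.59 in its other probe set), and Pparg, the master regulator of fat cell differentiation, was 1.40-fold lower.

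Genes of fatty acid synthesis from carbohydrate were lower as a list, and genes of cholesterol synthesis were higher. Of 21 measured de novo lipogenesis genes 13 were lower and 8 higher, with a median difference of -0.22 (0.02nd percentile). Beside Acaca, Mlxipl, which encodes the carbohydrate-responsive transcription factor ChREBP, was 2.46-fold lower, Fads1 1.91-fold and Fasn, the fatty acid synthase, 1.47-fold lower, although the other probe set of Fads1 differed by 0.021 and its direction depends on the probe set. Scd2, a fatty acid desaturase, went the other way and was 2.64-fold higher in 3 probe sets of one direction. Scd1 differed by 0.07 in its brighter probe set, from 9048.5 to 9516.9, and by 0.52 in its other, from 4528.5 to 6482.9. When each gene was represented by its probe set with the smallest difference, the median of this list was 0.0085 and the list no longer stood apart. In the cholesterol synthesis list 10 of 13 genes were higher, with a median difference of 0.28 (99.8th percentile). Hmgcs1, which makes the precursor of mevalonate, was 3.26-fold higher in 4 probe sets of one direction, Insig1, a sterol sensor partner, 2.31-fold and Mvk 1.70-fold higher, whereas Fdft1 was 1.49-fold lower. Mvk was weak on both arrays, at 32.3 on chow and 55 on the high-fat diet.

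The triglyceride synthesis and lipid droplet list had a median difference of 0.13 (87.5th percentile), with Mogat2 2.37-fold, Plin5 2.04-fold and Plin2, a lipid droplet coat gene, 1.68-fold higher. The other probe set of Plin5 differed by only 0.25. The lipolysis list had a median of 0.15 (82.3rd percentile), with Abhd5 1.54-fold lower and Prkar2b 1.60-fold higher. Fatty acid oxidation genes were higher in 12 of 15 cases with a median of 0.20 (97.9th percentile), led by Acadl at 1.51-fold, Slc25a20 at 1.39-fold and Cpt2 at 1.34-fold. This list was at the 96.9th percentile without Acadl and at the 94.5th with the probe set of smallest difference. In contrast, the lists of the TCA cycle and of branched-chain amino acid breakdown were lower by small amounts. The TCA cycle and pyruvate list had a median of -0.10 (1.96th percentile), with Pdha1 1.19-fold lower and Idh3a 1.34-fold higher, although the probe sets of Idh3a did not share a direction. In the branched-chain amino acid list 12 of 17 genes were lower, with a median of -0.20 (0.26th percentile), led by Bcat2, the first enzyme of this route, which was 1.59-fold lower. With plain probe sets only, the 3 lists were at the 87.2nd, 9.09th and 2.54th percentiles and none stood apart. The oxidative phosphorylation list had a median of -0.03 (3.04th percentile), with all 32 genes within 2-fold and Ndufa5 1.43-fold lower. It passed below the 2.5th percentile under quantile normalization and lowess centring and with plain probe sets. Brown and beige adipocyte markers had a median of -0.01 (54.4th percentile). Ucp1, the uncoupling protein of brown fat, was below the floor on both arrays, at 4.2 and 4.5, and of the 10 measured members 5 were higher and 5 lower. Cox8b was 1.80-fold and Elovl3 1.83-fold higher, while Dio2 was 1.42-fold and Fabp3 1.28-fold lower and Slc27a2 at least 2.08-fold lower. Elovl3 was just above the floor on chow, at 29.6, and its difference was as low as 0.39 under the alternatives.

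Genes of insulin signalling and glucose use were lower on the high-fat diet in 12 of 17 cases, with a median difference of -0.26 (0.14th percentile). The list also holds inhibitors of insulin signalling, such as Socs3 and Ptpn1, so its median gives no direction of the signalling itself. Pik3r1, the regulatory subunit of phosphoinositide kinase, was 2.18-fold lower in 4 probe sets of one direction, 2 of them under 2-fold. Irs2, an adaptor of the insulin receptor, was 1.98-fold lower in its only measured probe set, from 72.8 to 36.7. Hk2, a hexokinase, was 1.56-fold lower, and Slc2a4, the insulin-regulated glucose transporter, 1.42-fold lower, from 898.3 to 634. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 3.01-fold higher. With the probe set of smallest difference for each gene, the median was -0.11 and the list was within the random range, at the 5.55th percentile.

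Extracellular matrix genes were higher on the high-fat diet, in 22 of 27 cases, with a median difference of 0.44 (100th percentile). Thbs1 was the most different member. Postn, the gene of periostin, was 2.03-fold higher, and 3 chains of collagen VI were all higher, with Col6a2 at 1.95-fold, Col6a1 at 1.87-fold and Col6a3 at 1.43-fold. Col1a1, a chain of fibrillar collagen, was 1.67-fold higher, from 542.1 to 907.5. The 12 collagen genes alone, a choice made after the data were seen, had a median of 0.53 (100th percentile). Markers of adipocyte progenitors and fibroblasts were within the random range, with a median of 0.04 (72.8th percentile), but at the 98.6th percentile with the mean of all probe sets. Among them Mfap5 was 1.89-fold and Dpt 1.54-fold higher, and Pdgfra was 1.58-fold lower with probe sets that did not agree in direction.

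Genes of lipid-associated macrophages, the cells that gather around dying fat cells, were higher on the high-fat diet, while general macrophage markers were not. In the lipid-associated list 14 of 18 genes were higher, with a median difference of 0.45 (100th percentile). Fabp5, a fatty acid binding protein, was 2.09-fold higher, Atp6v0d2, a proton pump subunit, 2.06-fold, Mmp12, the macrophage elastase, 1.78-fold, and Itgax, which encodes CD11c, 1.66-fold higher, from 97.9 to 162.9. Atp6v0d2 was just above the floor on chow, at 29.3, its other probe set differed by 0.36, and it was under 2-fold in 5 alternatives. Several members, such as Fabp5, Lpl and the cathepsins, are also expressed by fat cells or other cells. Trem2 and Dcstamp, members more restricted to macrophages, differed by -0.72 and -0.51, and Cd5l was at least 2.27-fold lower. The general macrophage list had a median of 0.01 (53.7th percentile), with all 20 members within 2-fold, 10 higher and 10 lower. Adgre1, the gene of the F4/80 antigen, differed by 0.07 and Cd68 by 0.22. Cd14 was 1.56-fold lower, Cd163 1.45-fold and Mrc1, the mannose receptor of resident macrophages, 1.35-fold lower.

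Other immune lists stayed within the range of random lists. Inflammatory cytokines and chemokines had a median of 0.03 (72.2nd percentile), with Ccl11 1.54-fold and Cxcl9 1.44-fold higher and Il18 1.46-fold lower. Ccl2, a monocyte attractant, was at 66.3 and 70.9. Tnf was below the floor on both arrays, at 9 and 13.6. T and NK cell markers had a median of 0.05 (67.0th percentile), B cell markers -0.07 (36.5th), mast cell markers -0.10 (35.0th), MHC class II genes 0.18 (87.5th), interferon response genes -0.08 (34.6th) and NADPH oxidase genes -0.14 (22.1st). Among these, Jchain was 1.78-fold, Tpsb2 1.81-fold (-0.29 in its other probe set) and Oasl2 1.79-fold lower. Ighm, a B cell marker, was 1.49-fold higher, from 2765.2 to 4110.8, although its probe sets did not agree in direction. The neutrophil list had a median of 0.01 (61.0th percentile). Its member S100a8 was 4.82-fold higher, while S100a9, which encodes its partner protein, was at 32.9 on chow and below the floor on the high-fat diet at 3.5. Csf3r was 1.36-fold higher, and Ngp and Ltf differed by -0.08 and 0.07.

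**Figure D1:**
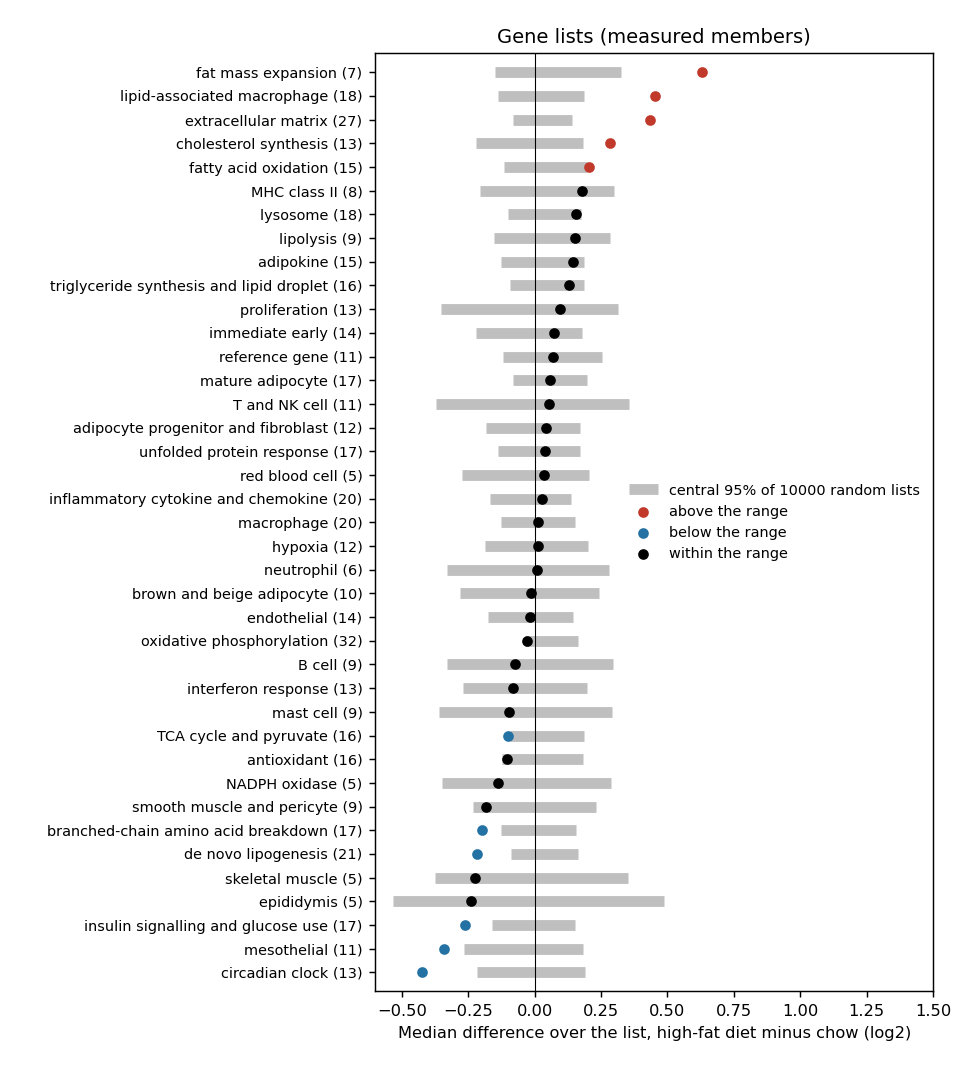
Median log2 difference of each of 39 gene lists between the high-fat diet and chow arrays (points, horizontal axis), with the number of measured genes in brackets and the central 95% of the medians of 10000 random lists matched on level (grey bars). Of the lists, 5 lie above their range, led by fat mass expansion at 0.63, and 6 lie below it, led by circadian clock at -0.42.

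Markers of other cells and tissues that a fat pad sample can hold were compared in the same way. Mesothelial markers, from the lining of the fat pad, were lower in 8 of 11 cases with a median of -0.34 (0.43rd percentile). Krt19 was 1.99-fold, Wt1 1.80-fold, Lrrn4 1.66-fold and Upk3b 1.62-fold lower. This list was within the random range with the floor at the 60th percentile (-0.25, just inside the limit) and with the probe set of smallest difference (10.3rd). Endothelial markers had a median of -0.02 (49.8th percentile), with Flt1 1.51-fold lower and Cldn5 1.23-fold higher. Smooth muscle and pericyte markers had a median of -0.18 (5.56th percentile), with Myh11 2.10-fold and Tagln 1.94-fold lower and Acta2 1.26-fold higher. Skeletal muscle markers had a median of -0.22 (11.2th percentile) over 5 genes, epididymis markers -0.24 (22.5th percentile) over 5 genes and red blood cell genes 0.03 (71.2nd percentile) over 5 genes. Only 4 testis germ cell genes were measured, and of these Gapdhs was 1.59-fold lower and Akap4 differed by -0.01.

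Circadian clock genes were lower on the high-fat diet in 10 of 13 cases, with a median difference of -0.42 (0.02nd percentile). Dbp and Hlf, output genes of the clock, were 1.72-fold and 1.67-fold lower (-1.45 in the other probe set of Hlf), and Ciart was 1.42-fold lower. Arntl, the core activator that peaks in the opposite phase, was 1.49-fold higher, with probe sets that differed in direction. The labels give no time of day for the sampling. Immediate early genes, which respond to handling and dissection, had a median of 0.07 (84.2nd percentile), with Nr4a1 1.59-fold lower and Egr3 1.57-fold higher.

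Stress and growth lists were within the range of random lists. Unfolded protein response genes had a median of 0.04 (65.3rd percentile), with Pdia4 1.99-fold lower (-0.23 in its other probe set) and Dnajb9 1.39-fold higher. Antioxidant genes had a median of -0.10 (3.99th percentile). In that list Gpx3, the secreted glutathione peroxidase, was 2.69-fold lower, from 5027 to 1869.5, Gsta3 was 2.33-fold lower (-0.37 in its other probe set) and Sod3, the extracellular superoxide dismutase, 1.96-fold higher. Hypoxia genes had a median of 0.01 (50.6th percentile), with Vegfa 1.29-fold lower. Lysosome genes had a median of 0.15 (95.3rd percentile, and 98.4th with the probe set of smallest difference), with Ctsd 1.56-fold and Ctsl 1.42-fold higher. Proliferation genes had a median of 0.10 (76.7th percentile), with Rrm2 1.59-fold and Top2a 1.54-fold higher at low intensities. The reference genes had a median of 0.07 (54.4th percentile), which was between -0.04 and 0.10 under the alternatives, but single members were not level, with Hprt 1.47-fold and Gusb 1.40-fold higher and Sdha 1.22-fold lower.

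**Figure D2:**
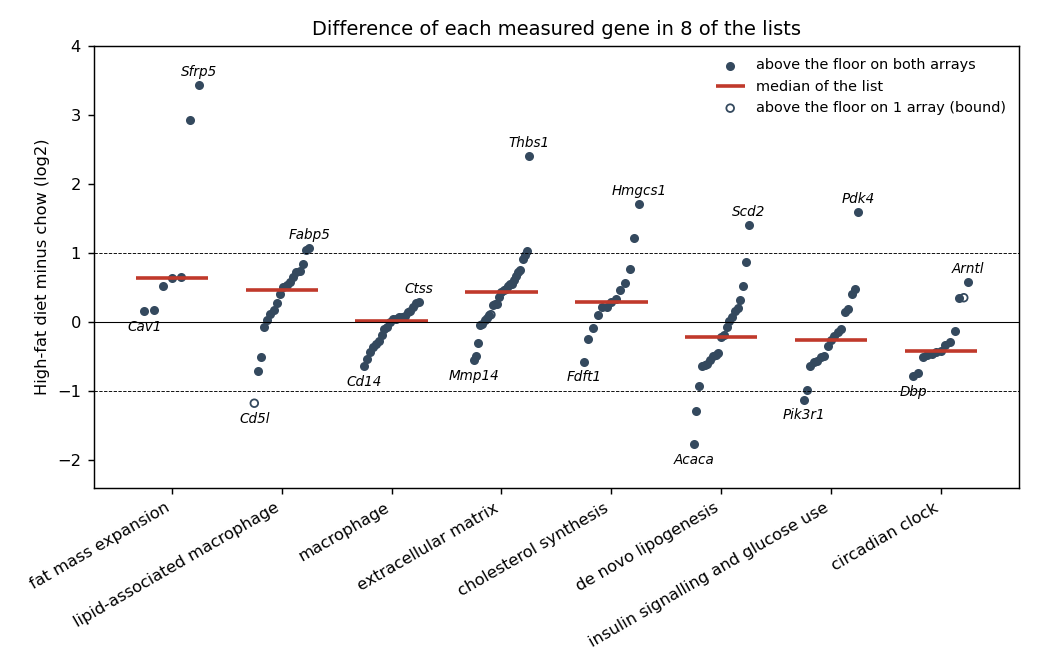
Log2 difference between the high-fat diet and chow arrays (vertical axis) for each measured gene of 8 lists, sorted within the list, with the list's median as a red bar; open circles are genes above the floor on 1 array, whose difference is a bound, and dashed lines mark 2-fold. The lipid-associated macrophage list has a median of 0.45 and the general macrophage list one of 0.01, and de novo lipogenesis ranges from Acaca to Scd2 on both sides of 0.

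Across the 39 lists with a percentile, 5 stood apart above and 6 below, where 1.95 would be outside the limits if lists were random draws. Genes of a list vary together within a sample, and mice on the same diet were not compared, so the number that would stand apart between them is not known. The mean and the median differed in sign for the macrophage, T and NK cell, brown and beige adipocyte, hypoxia, unfolded protein response and immediate early lists, whose medians were all near 0.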

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

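These probe sets were singled out after their values were seen, and no test was made. With 1 array per diet, no sample could be compared with others of its group. Probe sets without a gene name here were outside the gene comparisons, and among them 59 were 2-fold or more higher and 64 were 2-fold or more lower on the high-fat diet array than on the chow array. Among those above the floor on both arrays, the largest difference was in probe set 1420465_s_at, bright on chow at 3940.1 and at 203.4 on the high-fat diet, a difference of -4.28 log2 units or 19.4-fold lower. Probe set 1433334_at was lower by 4.55-fold, from 136.5 to 30, a difference of -2.19. Probe set 1445268_at was 9.37-fold higher, from 57.8 to 541.5, a difference of 3.23, and probe set 1429778_at was 2.93-fold higher, from 83.2 to 243.6, a difference of 1.55.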

How the results depend on the processing

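The restrictions to genes above the floor on both arrays, to brighter genes and to parts of lists (outside the 7 lists set as main results, also the removal of the most different member) were chosen after seeing the data. No paired analysis was possible because each diet has 1 sample, which also leaves no sample to leave out. Against 163 genes higher and 187 lower, the counts moved with the floor and with the size: a floor at the 25th percentile gave 429 and 545, at the 60th percentile 88 and 65, and no floor 1095 and 1216. A pseudocount of 50 gave 51 and 35, a size of 1.5-fold 808 and 890, and 3-fold 27 and 22. Requiring the floor on both arrays left 116 and 117, and a mean intensity of 100 or more left 79 and 58. The 4 other scalings and 3 other choices of probe set gave 112 to 176 genes higher and 136 to 251 lower. Weak signal near the floor thus limits the counts. With a higher floor fewer genes enter, 16035 at the 25th percentile and 10723 at the 60th, and more weak values are raised to the floor, which shrinks their differences. The pseudocount kept all 14066 genes and still lowered the counts. Of the 7 lists set as main results, the lipid-associated macrophage (median 0.31 to 0.51) and extracellular matrix (0.26 to 0.53) lists stood apart under every alternative run, and the macrophage, mature adipocyte and brown and beige adipocyte lists under none. The de novo lipogenesis list turned to 0.0085 with the probe set of smallest difference and no longer stood apart. This alternative picks small values by construction, but the lipid-associated macrophage and extracellular matrix lists still stood apart under it. The oxidative phosphorylation list stood apart at -0.13 under quantile normalization, -0.12 under lowess centring and -0.090 with plain probe sets; the cause was not tested. Among other lists, fat mass expansion, cholesterol synthesis and circadian clock stood apart under every alternative run. Of 186 named genes 23 changed sign under at least 1 alternative, 14 of them with the probe set of smallest difference. Only 1 of the 23, Pcnt, was 2-fold or more different, and it turned to 0.079 with its other probe set. Fabp5, Postn, Aqp7, Plin5 and Atp6v0d2 dropped under 2-fold when centred on the reference genes. With a pseudocount 8 named genes dropped under 2-fold, and with the probe set of smallest difference 11 came out under 2-fold, among them Acaca at -0.79. For Angpt1 and Ttr that value is a bound set by the floor, so a smaller difference was not measured.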

Other observations

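The lists of liver, pancreas and imprinted genes were chosen after the first results were seen, and the tests of clock phases and of the macrophage lists against each other were chosen after their result was seen. Beside Mest, the imprinted gene Peg3 was 3.45-fold higher on the high-fat diet, from 230.6 to 795.3, in 3 probe sets of one direction. Genes best known from the liver went both ways. Beside Apoa2 and Ttr, Serpina1c was 2.51-fold lower, Apoh 2.79-fold lower, and Apoa1 at least 2.99-fold lower and above the floor only on chow, whereas Cps1 was 1.41-fold and Cyp3a11 1.39-fold higher. Peg3 and these genes were named after their values were seen.

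One hypothesis was that the imprinted gene network, in which Mest and Peg3 are usually placed, was higher as a group. The 15 other measured members had a median difference of 0.090 (83.8th percentile of random lists), which leaves it undecided. Slc38a4, Peg10, Snrpn, Zim1, Phlda2 and Usp29 were below the floor on both arrays, and H19 had no probe set with its name here. These genes are outside the median. Plagl1 differed by 0.08, Nnat by 0.0086 and Igf2 by -0.28. The highest of the 15 was Ndn at 0.44, far from Mest and Peg3.

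The lower level of Apoa2, Ttr and Serpina1c might come from a trace of another organ in the chow sample. Pancreas is argued against by a list of 6 measured genes, whose median was 0.28 (95% bootstrap interval over genes -0.08 to 0.80); 6 more were below the floor on both arrays. Liver stays open: the median of 14 other liver genes, 9 lower and 5 higher, was -0.35, above the bound of -0.5 set against it, but the interval of -0.63 to 0.18 spans that bound, and the use of this interval was decided after the median was seen. Of the 9 lower genes 5 (Apoa1, Ahsg, Fga, Itih4 and Plg) were above the floor only on chow, so their differences are bounds and so is the median. The list had 20 genes, of which 1 had no probe set with its name here and 5, which are abundant in liver too, were below the floor on both arrays and outside the median: on chow Fgb was at 3, Fgg at 13.6, Ambp at 20.4, Mup3 at 20.8 in the brighter of its probe sets and Itih3 at 27.7. Albumin, among the most abundant liver transcripts, was at 141.5 on chow and 121.5 on the high-fat diet. An effect of the diet stays open as an untested explanation.

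The lipid-associated macrophage list was higher without the general macrophage list. For 8 of its genes, noise of the chosen probe sets is argued against by their other probe sets, whose median was 0.32 (99.1st percentile). The remaining genes, among them Itgax, Mmp12, Gpnmb, Trem2, Dcstamp and Cd5l, had 1 measured probe set each and are not covered. The medians of both lists differed by 0.44 (95% bootstrap interval over genes 0.07 to 0.75). This gap was seen before the comparison was chosen, so it is no separate test of more macrophages of all kinds. A first criterion, that the separate intervals of both lists do not overlap, was undecided and was replaced by the interval of the difference afterwards. The separate intervals overlapped in 70 of 100 repeats. General macrophage markers showed no common rise, with a median of 0.01 and 10 genes higher and 10 lower. A shift in macrophage state and higher expression of shared genes in fat cells may both contribute, and neither was tested.

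The clock list was lower on the high-fat diet. Noise of the chosen probe sets is argued against by the other probe sets of 8 genes, whose median was -0.46 (0.05th percentile). The 3 measured genes of the Arntl phase had a median of 0.35 and the 9 of the Dbp and Per phase one of -0.47, a difference of 0.82. The first median rests on little: it is the value of Cry1, a bound with chow below the floor, the other probe set of Arntl differed by -0.55, and the 4 probe sets of Clock did not share a direction. Sampling at different times of day and an effect of the diet on the clock could both give this, and they cannot be told apart with 1 sample per diet and no sampling time in the labels.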
